A study of Rattus norvegicus with 16 samples.

How the data were processed

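Frontal cortex DNA of 16 rats was cut with MspI, and fragments of 150 to 300 bp were bisulfite-treated and sequenced on a HiSeq 2500, per the labels' protocols. The submitters' processing notes name Bowtie and the build rn5, without versions, and the methylation caller is not given in the sources used here. The deposited files hold, per cytosine, a methylation fraction and the counts of methylated reads and of all reads. The authors' deposited fraction was not used for tests, which were made on the deposited read counts. No listed cytosine had under 10 reads in the deposited counts, so an alternative minimum under 10 could not be run. Reads carry no molecular identifiers, so limits from read counts cover counting error only.

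Groups were taken from the treatment label, with 4 rats per group. Each sample was taken as 1 rat, and the labels give no cage, litter or sequencing batch. No 2 samples of a group were the same library: over the 24 pairs the mean chi-square per region was 2.19 to 5.14, where 1 is sampling noise alone.

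Counts on both strands of a CpG were summed where both strands were listed. No strand with under 10 reads was listed, and only 127033 of the 958016 CpGs kept were covered on both strands in every rat. The strands counted could therefore differ between rats. A CpG was kept with at least 10 reads in each of the 16 samples, on chromosomes 1 to 20 and X, outside the 0.1% of highest coverage. A region was a run of at least 3 such CpGs with gaps of at most 100 bp and a length of at most 1000 bp. Counts per region were tested with a quasi-binomial logistic model over all 16 samples with 12 residual degrees of freedom, with a dispersion moderated across regions by limma 3.58.1 and held at 1 or more, and an F test of each contrast. P values were adjusted by Benjamini-Hochberg over all regions of a comparison, with a threshold of 0.05. Tested on simulated data for HFD+5-AzaD against HFD+PBS, with 200 of 110121 regions changed, the model recovered 54.5% of changes of 20 percentage points and 1.5% of changes of 10 points, and with no change it called 0 regions. Changes were placed only in regions of intermediate level. Each rat was drawn independently in each region, so variation that real rats share across regions was absent. The 0 calls therefore do not give the rate of false calls in the real data. The other comparisons were not simulated.

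Mean CpG methylation was the unweighted mean over kept CpGs. CA, CC and CT levels were methylated over all reads at the cytosines listed in each rat, not over a set shared by all rats. Groups were compared by exact two-sided permutation tests over 70 arrangements, whose smallest p is 0.0286, adjusted over 9 tests, with 95% intervals from inverting the test. Classes were tested likewise, adjusted over 5 classes, so a single class could not pass either. The named regions were, by a rule fixed before the data were examined, the 5 with the smallest p in each of the 3 main comparisons, since fewer than 5 passed. Comparisons, tests and most alternatives were fixed before the data were examined. Alternatives were other coverage rules, 300-bp tiles, single CpGs, CpGs alike on both strands, limma on logits with an offset of 0.5, edgeR 4.0.16, the 8 compared samples alone, no dispersion floor, and each rat left out in turn. Further alternatives were added after seeing the data: a principal component as a covariate, and other settings combined with leaving out HFD+5-AzaD replicate 2.

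An annotation of rn5 was not used here, so no region was assigned to a gene, and 17 gene lists and the promoter, exon and intron classes fixed beforehand were not tested. Analyses ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1.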

Results

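DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in the frontal cortex of 16 male Sprague Dawley rats, an outbred laboratory strain. RRBS cuts the genome with the enzyme MspI and reads methylation at single cytosines in CpG-rich fragments. The rats formed 4 groups of 4: a chow diet, a high fat diet (HFD), HFD with injections of phosphate-buffered saline (HFD+PBS, the vehicle), and HFD with injections of 5-aza-2′-deoxycytidine (HFD+5-AzaD), an inhibitor of DNA methyltransferases. Rats were 11 weeks old at the start, diets lasted 7 weeks and injections 10 days. The files listed between 374219903 and 628470043 reads at cytosines per rat, and HFD replicate 4 was the deepest. Of the CpGs that had at least 10 reads in all 16 rats, 958016 were kept, and 820929 of them fell into 110121 regions with a median of 5 CpGs, 135 bp and 263 CpG reads per rat.

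Most CpGs were either mostly methylated or mostly unmethylated. A mean level under 20% was found at 39.2% of CpGs, a level of 20 to 80% at 24.8% and a level over 80% at 36.0%. Outside CpG, methylation was highest at CA, with a mean of 1.82% ± 0.147 (SD, n = 16 rats). Within CA it was higher at CAC (3.64% ± 0.321, SD, n = 16) than at CAG (1.31% ± 0.0995, SD, n = 16). At CC directly before a CpG it was 0.340% ± 0.0150 (SD, n = 16), and on the mitochondrial chromosome outside CG it was 0.241% ± 0.0178 (SD, n = 16).

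The comparison of HFD with chow asked how the diet alone was related to cortical methylation. Mean CpG methylation was 48.1% ± 0.830 (SD, n = 4) under HFD and 48.3% ± 0.654 (SD, n = 4) under chow, a difference of -0.233 percentage points (95% interval -2.03 to 1.05; exact permutation test, two-sided p = 0.686, adjusted p = 0.882 over 9 tests). The sign of this difference turned over every CpG of a sample (0.333), in pooled reads (0.423), without chow replicate 4 (0.0708) and without HFD replicate 1 (0.0617), so no direction is given. CA methylation was 1.83% ± 0.0822 (SD, n = 4) and 1.94% ± 0.0866 (SD, n = 4), a difference of -0.107 points (95% interval -0.288 to 0.0887; exact permutation p = 0.143, adjusted p = 0.771). CC and CT methylation was 0.542% and 0.555% (exact permutation p = 0.429, adjusted p = 0.771). None of these differences passed the test, although that in CA was larger than the SD of either group. After adjustment over 9 tests, a single test could not have passed even with the groups fully apart.

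No region passed an adjusted p of 0.05 in the quasi-binomial logistic model of HFD against chow. At an unadjusted p under 0.05 there were 7487 regions, against 5506 from chance alone. With single rats left out this number ran from 5130 (without HFD replicate 4) to 8807 (without HFD replicate 3), so no excess is claimed. Of the other methods, edgeR called 0 regions and limma 2. The 5 regions with the smallest p, none past the threshold, are given here with rn5 coordinates. On chromosome 3 from 141136548 to 141136775 (10 CpGs, 342 to 648 reads per rat) the level was 91.6% ± 1.92 (SD, n = 4) under HFD and 82.1% ± 2.63 (SD, n = 4) under chow, with an adjusted p of 0.537 in the quasi-binomial model with limma's moderated dispersion. On chromosome 6 from 93226051 to 93226263 it was 72.5% ± 4.04 and 84.2% ± 1.81, and on chromosome 4 from 191147609 to 191147749 it was 51.4% ± 1.13 and 65.8% ± 2.14 (SD, n = 4 each). On chromosome 17 from 13845290 to 13845509 it was 77.7% ± 2.67 and 86.1% ± 1.39 (SD, n = 4 each). On chromosome 10 from 107854775 to 107854849 no methylated read was seen in the 4 HFD rats, while chow rats had 5.24% ± 1.75 (SD, n = 4). On the same diet, HFD+PBS rats had 3.78% ± 0.64 and HFD+5-AzaD rats 1.03% ± 0.71 there (SD, n = 4 each). At each of the 5 regions the means of both injected groups lay between those of HFD and chow. The regions were picked for the difference between HFD and chow, so these levels cannot decide whether they followed diet. The reads of the HFD rats in that region allow a level of up to 0.602%, for counting error only, and this region was 1 of the 2 that limma called.

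The comparison of HFD+5-AzaD with HFD+PBS asked what the inhibitor was related to beyond its vehicle under the same diet. Mean CpG methylation was 47.4% ± 0.999 (SD, n = 4) with the drug and 47.5% ± 0.280 (SD, n = 4) with the vehicle, a difference of -0.0356 points (95% interval -1.70 to 1.34; exact permutation p = 0.914, adjusted p = 0.914). The sign turned in 3 alternatives, to between 0.0174 and 0.386, so no direction is given. CA methylation was 1.69% ± 0.170 (SD, n = 4) and 1.81% ± 0.147 (SD, n = 4), a difference of -0.123 points (95% interval -0.396 to 0.320; exact permutation p = 0.400, adjusted p = 0.771). CC and CT methylation was 0.508% and 0.529% (exact permutation p = 0.371, adjusted p = 0.771).

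**Figure D1:**
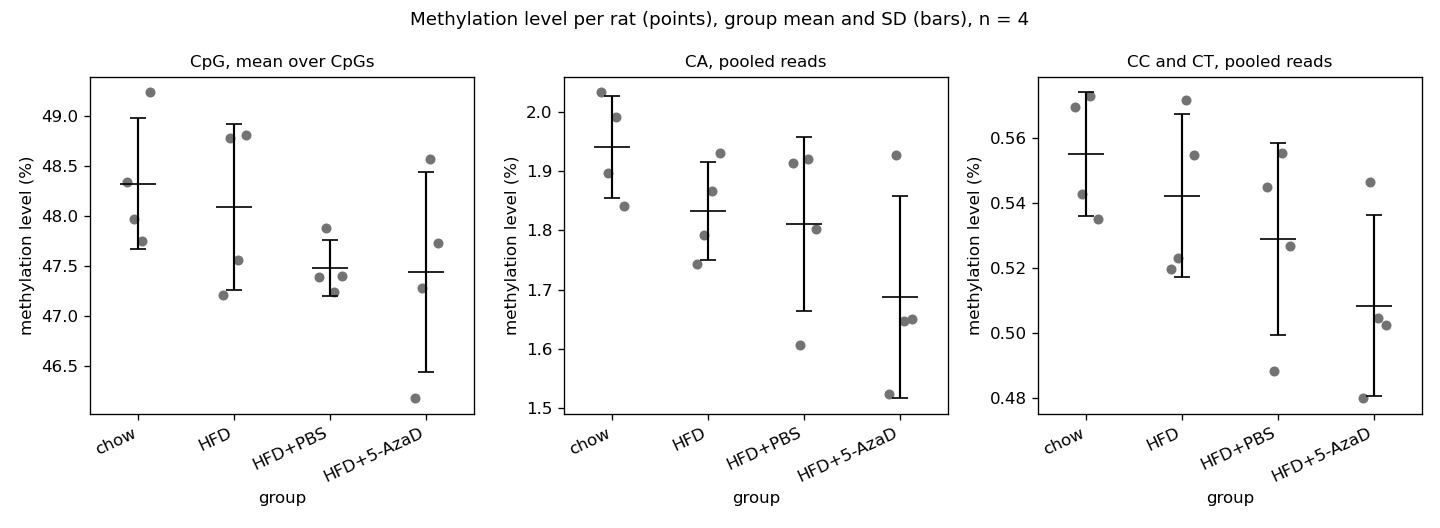
Methylation level per rat in percent (vertical axis) by group (horizontal axis), for CpG, for CA and for CC and CT; points are rats, bars the group mean and SD with n = 4. The groups overlap in each panel, with mean CpG levels from 47.4% under HFD+5-AzaD to 48.3% under chow; the vertical axes do not start at 0.

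No region passed in the quasi-binomial logistic model of HFD+5-AzaD against HFD+PBS. At an unadjusted p under 0.05 there were 6604 regions, against 5506 from chance alone. With single rats left out this number ran from 4791 (without HFD+5-AzaD replicate 3) to 9838 (without HFD+5-AzaD replicate 2), so no excess is claimed. Of the other methods, edgeR and limma each called 0 regions. The 5 regions with the smallest p all had the lower level with the drug, and none passed; over all regions 50.7% were lower, with a median difference of -0.0139 points. The first, on chromosome 16 from 68769920 to 68770104 (14 CpGs, 662 to 935 reads per rat), had 34.5% ± 1.91 (SD, n = 4) with the drug and 45.9% ± 2.32 (SD, n = 4) with the vehicle, with an adjusted p of 0.202 in the quasi-binomial model with limma's moderated dispersion. On chromosome 6 from 102474061 to 102474207 the levels were 66.3% ± 2.98 and 79.4% ± 2.83, and on chromosome 1 from 20933714 to 20933767 they were 47.3% ± 6.20 and 69.2% ± 0.83 (SD, n = 4 each). On chromosome 15 from 32215589 to 32216000 they were 54.8% ± 3.03 and 65.1% ± 3.02, and on chromosome 14 from 83163451 to 83163543 they were 66.8% ± 1.96 and 79.3% ± 2.07 (SD, n = 4 each). Rats on HFD without injections had means of 46.4%, 71.3%, 59.4%, 59.4% and 73.5% at these 5 regions, in the same order. The drug group had the lowest mean of the 4 groups at each. At all but the first, the vehicle group had the highest mean, so part of those gaps reflects a high vehicle level. The count depended on 1 rat: without HFD+5-AzaD replicate 2 the same model called 105 regions, 103 of them lower with the drug, while edgeR then called 6 and limma 0, and leaving out any of the 7 other rats gave 0.

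The comparison of HFD+PBS with HFD asked what the injections of vehicle were related to. Mean CpG methylation was 47.5% ± 0.280 (SD, n = 4) with injections and 48.1% ± 0.830 (SD, n = 4) without, a difference of -0.614 points (95% interval -1.57 to 0.674; exact permutation p = 0.286, adjusted p = 0.771). CA methylation was 1.81% and 1.83% (exact permutation test, adjusted p = 0.914), and CC and CT methylation was 0.529% and 0.542% (exact permutation p = 0.571, adjusted p = 0.857).

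No region passed in the quasi-binomial logistic model of HFD+PBS against HFD, with 7162 regions at an unadjusted p under 0.05, 0 calls by edgeR and 1 by limma. The smallest p, on chromosome 6 from 139221244 to 139221358 (4 CpGs, 93 to 515 reads per rat), belonged to levels of 83.7% ± 1.89 (SD, n = 4) with injections and 62.3% ± 15.4 (SD, n = 4) without, with an adjusted p of 0.760 in the quasi-binomial model with limma's moderated dispersion. Without HFD replicate 1 this region alone passed, with a difference of 29.1 points and an adjusted p of 0.00259 in that model. HFD replicate 1 had 85.1% there, within the range of the vehicle rats (81.5% to 86.1%). That call thus rests on leaving out the rat that went against the difference. On chromosome 12 from 49369106 to 49369193 the levels were 68.0% ± 4.10 and 80.2% ± 3.30, and on chromosome 10 from 102345995 to 102346217 they were 78.1% ± 1.79 and 90.6% ± 3.55 (SD, n = 4 each). On chromosome 2 from 41530393 to 41530480 they were 61.6% ± 6.01 and 81.3% ± 4.86, and on chromosome 17 from 34688620 to 34688708 they were 80.4% ± 0.49 and 75.2% ± 1.59 (SD, n = 4 each). The HFD+5-AzaD rats, injected with the drug in PBS, had means of 63.4% on chromosome 6, 79.6% on chromosome 12 and 80.7% on chromosome 10. On chromosomes 2 and 17 these rats had 57.5% and 78.3%. Their means were near those without injections on chromosomes 6 and 12, but not on chromosomes 10 and 2. The regions were picked for HFD+PBS against HFD, so these levels cannot decide whether the regions followed the injections. HFD+PBS against chow, which differ in both diet and injections, also gave 0 regions in the quasi-binomial model, with 6147 at an unadjusted p under 0.05, 0 calls by edgeR and 1 by limma.

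**Figure D2:**
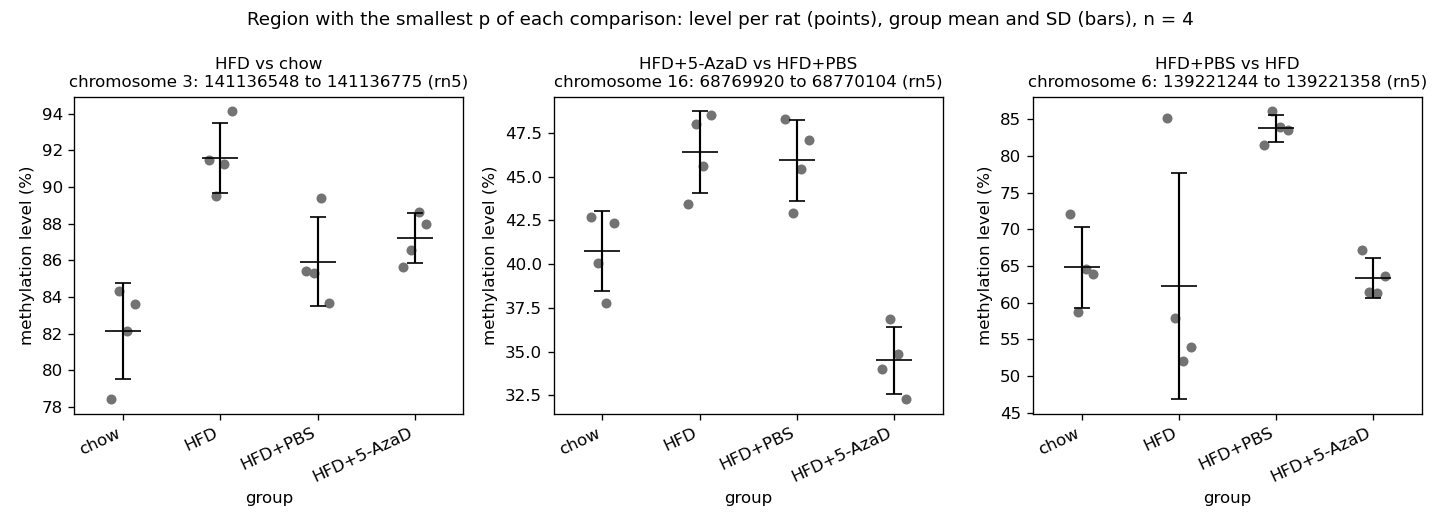
Methylation level per rat in percent (vertical axis) by group (horizontal axis) at the region with the smallest p of each main comparison; points are rats, bars the group mean and SD with n = 4. The level on chromosome 16 is 34.5% with the drug and 45.9% with the vehicle, and none of the 3 regions passed the threshold; the vertical axes do not start at 0.

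Regions were divided into CpG-dense and CpG-sparse ones and by mean level. None of the 5 classes passed in any of the 3 main comparisons. After adjustment, a change in a single class could not have passed even at the smallest possible exact permutation p of 0.0286. The smallest exact permutation p found was 0.171, for regions under 20% in HFD+PBS against HFD (adjusted p = 0.286). In that class the level was 2.82% ± 0.189 (SD, n = 4) with injections and 3.09% ± 0.327 (SD, n = 4) without. In regions of 20 to 80% the level was 59.0% ± 2.70 (SD, n = 4) with the drug and 58.9% ± 1.02 (SD, n = 4) with the vehicle.

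A last comparison asked whether the drug moved regions against the direction of the diet. Across 110121 regions, which are not independent replicates, the difference between HFD and chow had a Pearson correlation of -0.0183 with the difference between HFD+5-AzaD and HFD+PBS (exact permutation of labels, p = 0.887) and a Spearman correlation of -0.0152 (exact permutation p = 0.883). These 2 differences share no rat. Over the 4900 arrangements of labels the Pearson correlation reached 0.493 in size, so the small value found does not exclude an opposing relation.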

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

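All tests of explanations in this part were chosen after the results that they explain were seen. The predictions were written before the test itself was run only for 4 of them. These were the strand test, the test without 1 CpG, the 12 splits with rats left out in turn and the 100 triples. Samples far from the other 3 of their group were sought in 33 measures and 4 groups, 132 sets of 4, of which chance alone would give about 6.6. There were 7, so their number was close to that from chance.

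HFD+PBS replicate 2 stood apart in the mean over regions under 20%, at 3.11% against 2.73% at most in the other 3 rats (gap over range 0.989). HFD replicate 4 had 628470043 reads at cytosines, and its gap over range was 0.890. HFD+5-AzaD replicate 2 had a mitochondrial CpG level of 0.323% against 0.360% or more (gap over range 0.912). Single named regions gave HFD+5-AzaD replicate 4 on chromosome 6 from 93226051 (gap over range 0.871), chow replicate 2 on chromosome 15 from 32215589 (0.842) and HFD+PBS replicate 2 on chromosome 17 from 34688620 (0.898).

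HFD+5-AzaD replicate 2 also stood apart on the second principal component of regions of 20 to 80%, at 157 against -778 to -748 in the other 3 rats of its group (gap over range 0.968). The 12 rats without the drug lay at -130 to 803, so it sat among them, and the other 3 drug-treated rats stood apart from all 13 rats. This component held 10.8% of the variance, and the groups differed on it (permutation test of the F ratio, p = 0.0175, adjusted p = 0.0351 over 2 components). Leaving it out gave 105 regions where all rats gave 0. It was singled out because of that count, as 1 of 32 fits that left out a rat, so the 105 regions are a pattern chosen by its outcome and not a measured drug effect. Over the 103 lower regions the other drug-treated rats had mean levels of 45.1%, 41.6% and 44.5%, the 8 rats without injections 55.6% to 59.9% and the 4 vehicle rats 60.6% to 64.3%. The vehicle rats thus all lay above the rats without injections, so part of the fall against the vehicle reflects a high vehicle group, in regions picked for that fall.

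The left-out rat had 60.3%, with a median difference from the vehicle mean of -1.39 points against -17.5 for the rats that entered, and it lay below the vehicle mean in 70 of the 103 regions. At the 4 of them that are also among the 5 of smallest p with all rats, which this rat helped to rank, it was lower than the vehicle group: 36.9% against 45.9% (chromosome 16), 70.6% against 79.4% (chromosome 6), 56.3% against 69.2% (chromosome 1) and 56.8% against 65.1% (chromosome 15). Because the fit was picked by what leaving this rat out gave, its values cannot decide whether a drug effect was shared by all 4 rats. Falls were similar on both strands (ratio of the medians 0.807, over 94 regions), but a variant at a CpG removes it on both strands, so this cannot decide about base variants. A base variant at 1 CpG of each region is argued against, since without the CpG of largest fall the median fall was 16.01 points against 17.25 with it (ratio 0.928), and 742 of 753 CpGs were lower. On the first principal component 2 of the 3 rats lay above the mean of the 13 others and 1 below. Any 3 rats often fall on both sides of a mean, so this cannot decide whether that component was the cause. The second, on which the 3 rats stood together, stays open too. Without regard to how the rat was picked, 1 of the 35 splits of the 7 samples gave as many regions, the real one, and the highest of the other splits gave 2. When each of the 8 rats was left out in turn in 12 splits, 3 splits reached the real 105, with 219 in the highest other; 12 splits are too few for a share under 0.05. Among 100 triples of rats set against the 13 others, 1 reached the 606 regions of these 3 rats, but they were picked for the pattern, and the highest other triple (chow replicate 4, HFD replicate 2 and HFD+5-AzaD replicate 3, the highest rats on the first principal component) gave 519. A shared drug effect, a rat that did not respond, a wrong label, chance, and kinship or shared handling of the 3 rats, which was not tested, all stay open.

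With all rats, 35 of 35 splits gave as many regions as each of the 4 comparisons, since the real count was 0, and the highest other counts were 1 for HFD against chow, 1 for HFD+5-AzaD against HFD+PBS, 2 for HFD+PBS against HFD and 3 for HFD+PBS against chow.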

How the results depend on the processing

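The alternatives combined with leaving out HFD+5-AzaD replicate 2, and the principal component as a covariate, were chosen after seeing the data. An alternative minimum of 5 reads was not run, since no cytosine under 10 reads was listed; gene lists were not tested. Counts of regions were 0 under every alternative fixed beforehand that kept all rats, except with limma: 2 for HFD against chow, 1 for HFD+PBS against HFD and 1 for HFD+PBS against chow. Of these, 3 were differences under 1 point (-0.44, 0.61 and -0.57), and the first and second are the same region on chromosome 9 from 93250848. With the component as a covariate limma called 3, 2 and 0. With rats left out in turn the counts ranged from 0 to 105 for HFD+5-AzaD against HFD+PBS (105 only without HFD+5-AzaD replicate 2), from 0 to 1 for HFD+PBS against HFD (1 without HFD replicate 1), and were 0 otherwise. Without HFD+5-AzaD replicate 2, the count was 114 with no floor, 114 at 20 reads, 97 with 3 of 4 samples, 106 with no upper limit, 82 in tiles and 104 on autosomes. It was 20 in CpGs alike on both strands, but there only 15478 regions were tested in place of 110121. The count fell to 6 with edgeR and to 2 when only the 7 compared samples set the dispersion. It was 0 with limma and with limma and the component, so it depends on the model. Single CpGs also gave 0, but under the same quasi-binomial model and with 958016 units tested. The cause was not tested.

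None of the mean levels passed under any alternative, but none could have. Each alternative replaced a single p value of the 9 before adjustment. Even the smallest possible exact permutation p of 0.0286 would then not have passed, so this is no evidence of robustness. Mean CpG methylation of HFD against chow changed sign, to 0.333 points over every CpG of a sample and to 0.423 in pooled reads. For HFD+5-AzaD against HFD+PBS it moved from -0.0356 to -0.166 and -0.588 under these settings, and for HFD+PBS against HFD from -0.614 to -1.28 and -1.22; the cause was not tested. With rats left out, mean CpG ranged from -0.474 to 0.0708 for HFD against chow, from -0.413 to 0.386 for HFD+5-AzaD against HFD+PBS and from -0.908 to -0.373 for HFD+PBS against HFD. In the same order, CA ranged from -0.140 to -0.0766, from -0.203 to -0.0687 and from -0.0591 to 0.0457, and CC and CT from -0.0225 to -0.00515, from -0.0340 to -0.0109 and from -0.0223 to 5.75e-05. The correlation of diet and drug differences ranged from -0.0928 to 0.0620 with rats left out. Title numbers did not pair the rats of HFD+PBS and chow (correlations of deviations 0.0610, -0.0180, 0.101 and -0.0177), and with them as a replicate block limma called 0 regions over these 8 samples, as it did over the 8 samples without the block.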

Other observations

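All tests in this part were chosen after the values were seen. The first principal component over 36703 regions of 20 to 80% held 26.7% of the variance, and no difference between the groups was detected on it (permutation test of the F ratio, p = 0.632), with HFD+5-AzaD replicates 1 and 3 at its opposite ends (-773 and 1312). Its Spearman correlation with the share of reads in low-methylated regions was -0.212 (permutation p = 0.430, Pearson r = -0.259, permutation p = 0.356; r = 0.079 without the 2 rats farthest from the median), which leaves library composition open. With sequencing depth the Spearman correlation was 0.632 (permutation p = 0.0109, adjusted p = 0.0327 over 3 relations; Pearson r = 0.473, permutation p = 0.0373; r = 0.642 without the 2 farthest), so depth, or something that varied with it, is a candidate explanation. A difference in dissection or cell mixture was not tested.

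CA methylation varied between rats from 1.52% to 2.03%. It was pooled over the CA cytosines listed in each rat, from 2873554 in HFD+5-AzaD replicate 1 to 3347794 in HFD replicate 4. HFD+5-AzaD replicate 1 was the lowest in CA and had the highest share of reads in low-methylated regions (50.5%). Library composition was not tested for CA and stays open. Incomplete conversion would move cytosines before a CpG as much, and their SD was 0.102 of that at CA, which argues against it. The Spearman correlation with sequencing depth was 0.156 (permutation p = 0.566; Pearson r = 0.203, permutation p = 0.481; r = 0.125 without the 2 farthest), which leaves depth open. The 4 chow rats had 1.94% ± 0.0866 (SD) and the 12 rats on HFD 1.78% ± 0.142 (SD), with an exact permutation p of 0.0473 over 1820 arrangements. These 12 rats pool HFD alone (1.83%), the vehicle (1.81%) and the drug (1.69%), the drug group being the lowest. Within the drug group HFD+5-AzaD replicate 2 had 1.93%, against 1.92% at most in the vehicle group, and the others 1.52% to 1.65%; without it the difference between drug and vehicle moved from -0.123 to -0.203 points. HFD alone differed from chow by -0.107 points. Setting 4 rats against 12 was tried after the levels were seen, so a lower CA level under HFD is not shown here. None of the 9 planned tests passed, but a single one of them could not have, even with the groups fully apart. Diet and drug are not separated in the difference of the 4 rats from the 12.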
